A study of Caenorhabditis elegans with 2 samples.

How the data were processed

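Chromatin from whole transgenic young adult worms, 64 h old, was sonicated and precipitated with an antibody against green fluorescent protein, per the labels. The 2 samples are biological replicates of 1 group, and the labels name a control experiment that was not used here. Per the file headers, reads were aligned to the build ce11 separately for each replicate. The aligner, the peak caller and the settings are not given in the sources used here. The deposited lists come in 2 kinds, ranked and thresholded by the irreproducible discovery rate (IDR), a measure of how well peak ranks repeat between replicates or parts of 1 replicate. For both replicates together there is a thresholded list, used here as the main list, a conservative thresholded list, and the ranked list behind each. Each replicate has its own ranked and thresholded list. Per the file headers, the thresholded lists also derive from a further file that the ranked lists do not derive from, and its content is not named.

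Each deposited peak carries a signal value from the authors' peak caller, whose normalization is not stated. It was used to rank and describe peaks within a list, to compare places or groups of regions within a list, and for a rank correlation between the replicates. Each deposited peak also carries a score, up to a ceiling, that rises with reproducibility, and no thresholded list held a score under 830. The ranked lists carry the −log10 of the global IDR as the authors computed it. The ranked list behind the main list held 112494 peaks, of which 1.26% were in the main list. The own ranked lists held 52508 peaks for replicate 1 and 70327 for replicate 2. No read counts are in the files, so depth per sample is unknown, and intervals on shares cover the counting of regions only.

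The highest peak end on each chromosome lay inside the chromosome lengths of the reference sequence, which is the same assembly as ce11. Genes were taken from Ensembl release 115. Listed peaks that shared at least 1 bp were merged into 1 region, whose summit was that of the listed peak with the highest signal value. This gave 1374 regions from 1419 peaks of the main list and 1029 from 1062 of the conservative list. Merged regions of the 2 lists overlapped in 870 cases. Positions are given counted from 1.

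Overlap between replicates counted regions that shared 1 bp or more, against 100000 random placements within chromosomes in a one-sided permutation test. Shares of promoters (1000 bp upstream to 200 bp downstream of the 5' end of a protein-coding gene), chromosomes and gene classes were set against the share of genome bases, or for gene classes of start positions at which a region of the median width would overlap, in exact binomial tests. Motifs were sought on both strands in windows of 101 bp at summits and in 2 flank windows per region centred 500 bp to either side, with Fisher's exact test. All 8-mers present in at least 10 windows were tested in the same windows, one-sided. Each region gave at most 1 target gene, the one with the nearest 5' end among the promoter windows holding the summit. Each of 25 gene lists was compared with all other protein-coding genes by Fisher's exact test. Tests were two-sided unless stated, with Benjamini-Hochberg adjustment within each family and a threshold of 0.05. Such tests treat regions as independent and measure no spread between animals.

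Apart from the additions named below, the tests, the motifs, the gene lists and the rule for named regions were set before the data were examined. The rule took the 20 regions of highest signal, the region nearest to cebp-2, up to 4 targets by signal of each enriched list, up to 8 targets each of the irg, bZIP and aminoacyl-tRNA synthetase lists, and the 10 8-mers of lowest p. The gene lists covered immune, stress, metabolic, structural and regulatory genes and markers of intestine, muscle, neurons, germline and hypodermis. They were made by gene symbol, so family members with another kind of name were left out. The heat shock list thus did not hold F44E5.4, a target of the Hsp70 family described below. Of the lists not described below, heat shock proteins (1 of 22), lipid metabolism (1 of 89), vitellogenins (0 of 6), detoxification (4 of 185), collagens (1 of 156), nuclear receptors (3 of 269), ceh homeobox genes (1 of 63), amino acid and one-carbon metabolism (0 of 19), and intestine (1 of 15), muscle (0 of 14), neuron (0 of 18), germline (2 of 27) and hypodermis (0 of 14) markers had the number of targets given and did not pass the test.

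Alternatives used the conservative list, the regions above the median signal, the own list of each replicate, unmerged peaks, other promoter and motif windows, other control windows, another background and 6-mers. The gene classes, the alternatives for the share on IV, the overlap of replicates against random peaks of the ranked lists, the scan of 500 kb windows, the GC-matched control windows and the exclusion of regions in dense windows or at small RNA genes were added after the data had been seen. Also not among the tests set beforehand were those of introns, exons and sequence outside genes. The same holds for the tests of the number of regions within 50 kb of cebp-2 and of the signal at small RNA genes. The GC-matched control drew 10 random genome windows per region and covered 1371 regions.

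The functions were tested on simulated data. In 1374 simulated regions with TTGCGCAA planted in 13.4% of summits, the motif was recovered in 13.7%, was the first 8-mer, and 0 unrelated motifs passed. The simulated regions were placed at random inside or outside promoters and were not given the GC content of the real summits (48.0% against 37.0% in the flanks). The count of unrelated motifs therefore cannot show whether that difference leads to motif calls in the real data. All 30 ribosomal protein promoters placed among them were recovered and 0 other lists passed. When the same 8-mer was planted in the real summit windows, the C/EBP test called an excess in 20 of 20 draws at 3.0% of regions planted, in 11 at 2.0% and in 0 at 1.0%. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.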

Results

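Binding of CEBP-2 was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in whole young adult Caenorhabditis elegans, 64 h old and synchronised as starved L1 larvae. CEBP-2 is a basic leucine zipper (bZIP) protein of the C/EBP family. The worms were of strain OP331, which carries a transgene in which the cebp-2 gene is fused to green fluorescent protein and epitope tags, and the tagged protein was precipitated with an antibody against green fluorescent protein. The series holds 1 group with 2 biological replicates. No control immunoprecipitation was analysed here, so no comparison below sets the peaks against a control. Comparisons are with the genome, with flanking or other windows, between sets of genes, between groups of regions or peaks, or between replicates. The files hold called peaks and no read counts, so sequencing depth is unknown. All positions refer to the build ce11. The main list, called by the authors on both replicates together, held 1419 peaks in 1374 separate regions that covered 0.377% of the genome.

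The replicates shared more regions than random placement gives. The list of replicate 1 alone held 246 regions and that of replicate 2 alone held 382. Of the regions of replicate 1, 136 (55.3%, 95% Wilson interval 49.04 to 61.37%) overlapped a region of replicate 2, against 0.211% on average when the regions were placed at random. The same number is 35.6% (31.0 to 40.5%) of the regions of replicate 2, against 0.135% at random. In the one-sided permutation test p was 1e-05 in both directions, the smallest that 100000 placements can give. Of the main regions, 134 lay in both replicates' own lists and 916 (66.7%) in neither, so most of the main list rests on the analysis of both replicates together. Across the 1313 main regions with a peak in both ranked lists, the signal values of the replicates had a Spearman rho of 0.204. Regions are not independent replicates, and all of them had been selected for high signal.

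The 20 regions with the highest signal in the main list were present in both replicates' own lists, and 3 of them lay at the promoter of a protein-coding gene. The highest signal value of the main list, 390.5, was at chromosome V, 8500487 to 8500657, in an intron of the peroxidasin gene pxn-1 that also holds the small nucleolar RNA (snoRNA) gene ZK994.7. The next, 377.8, lay in an intron of frm-7 at V, 12303546 to 12303726, over the snoRNA genes C51F7.3 and C51F7.4. Regions in introns of rbm-34 (IV, 12086585 to 12086682) and of the Mediator subunit gene mdt-26 (II, 5661755 to 5661916) had values of 289.4 and 288.0. The 3 promoter regions belonged to rpl-3, F44E5.4 and fbxa-83. The first lay 291 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit, at III, 3867507 to 3867638, with a value of 284.1. The second lay 149 bp upstream of F44E5.4, a gene of the Hsp70 chaperone family, at II, 11759380 to 11759491, with a value of 278.8. The third lay 722 bp upstream of fbxa-83 and overlapped the snoRNA gene Y67A10A.14 (IV, 14326970 to 14327239; 229.3). A region of value 251.8 at I, 13463883 to 13463984 lay in ints-8 over rpr-1, the gene for the RNA of RNase P. Other intronic regions were in mom-1 (X, 6296528 to 6296626; 264.3), cmk-1 (IV, 1831259 to 1831528; 236.2) and cutl-18 (V, 11314085 to 11314354; 212.4), the last over the snoRNA gene T03F7.8. The remaining 9 of the 20 regions lay outside protein-coding genes, with no target gene, at values from 212.3 to 268.1. Their starts were II 11960768, IV 15059212 (over the non-coding RNA gene Y41E3.460), IV 4725567, and X 4209238, 11094142, 16056491, 13700760, 17442622 and 806563.

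Regions were more frequent at promoters than bases of the genome are. Summits lay between 1000 bp upstream and 200 bp downstream of the 5' end of a protein-coding gene in 407 of 1374 regions (29.6%, Wilson interval 27.3 to 32.1%), against 21.5% of genome bases (exact binomial test, two-sided, p = 1.3e-12). In the replicates' own lists the share was 35.2% ± 3.12 (SD, n = 2). Introns held fewer summits than their share of the genome, 23.9% against 33.3% (exact binomial test, adjusted p = 1.7e-13). Sequence outside protein-coding genes held more, 43.5% against 37.3% (exact adjusted p = 6.8e-06). Coding exons held 26.7% of summits against 24.6% of bases (exact adjusted p = 0.093), but 13.0% and 14.9% in the lists of replicates 1 and 2. The 5' untranslated regions held 31 summits, 2.26% against 1.43% (exact adjusted p = 0.027), and 2.03% and 1.83% in those lists. The 3' untranslated regions held 3.64% against 3.32% (exact adjusted p = 0.50).

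Genes for 3 classes of small RNA, described here in turn, were overlapped by 236 of the 1374 regions (17.2%), and by 24.0% and 31.2% of the regions in the own lists of replicates 1 and 2. These gene classes were chosen after the enriched sequences described below had been seen. Transfer RNA (tRNA) genes were overlapped by 161 regions (11.7%, Wilson interval 10.1 to 13.5%) against 0.202% for random placement (exact binomial test, p = 1.7e-221), and 177 of 612 annotated tRNA genes were covered. In the replicates' own lists the share was 14.2% ± 5.77 (SD, n = 2). Regions also overlapped snoRNA genes (58 regions, 4.22% against 0.139%, exact p = 3.7e-64; 12.6% and 10.5% in the own lists) and small nuclear RNA (snRNA) genes (17 regions, 1.24% against 0.0493%, p = 1.8e-18; 1.22% and 2.36%). The genes for piRNAs, the small RNAs that act with Piwi proteins in the germline, went the other way, with 15 regions or 1.09% against 2.66% (exact adjusted p = 0.00012 over 8 gene classes). Pseudogenes were also overlapped less often than by random placement (30 regions, 2.18% against 3.76%, exact adjusted p = 0.0018). Genes annotated as other non-coding RNAs were overlapped by 226 regions (16.4% against 2.75%, exact adjusted p = 1.5e-101), of which 129 also overlapped a tRNA, snoRNA or snRNA gene. Genes for microRNAs were overlapped by 5 regions (0.364% against 0.0881%, exact adjusted p = 0.0091). In the own lists of replicates 1 and 2 the piRNA gene share was 2.44% and 0.785%. The 236 regions at tRNA, snoRNA or snRNA genes had a median signal of 93.6, against 75.8 for the other 1138 regions (permutation test, two-sided, 100000 resamples, p = 1e-05, the smallest these can give).

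**Figure D1:**
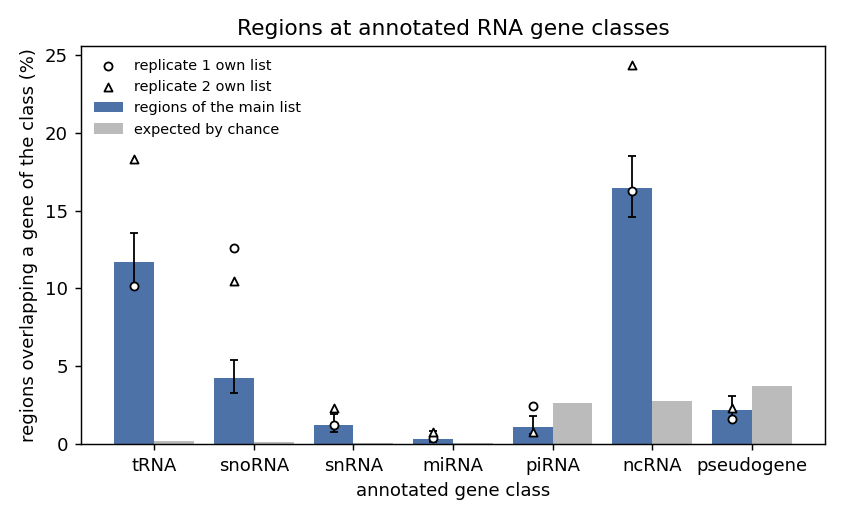
Percent of regions of the main list that overlap annotated genes of 7 classes (blue bars, with 95% Wilson intervals) beside the percent expected for random placement (grey bars); circles and triangles give the own lists of replicates 1 and 2. tRNA genes were overlapped by 11.7% of regions against 0.202% expected, and piRNA genes by 1.09% against 2.66%.

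Chromosome IV held more regions than its length and V fewer. IV held 366 regions (26.6%, Wilson interval 24.4 to 29.0%) against 17.4% of genome bases, with an adjusted p of 1.4e-16 over 6 chromosomes in the exact binomial test. V held 207 (15.1% against 20.9%, exact adjusted p = 1.5e-07). X held 215 regions, 15.6% (13.8 to 17.7%) against 17.7% (exact p = 0.052, adjusted p = 0.10), and the own lists gave 17.7% ± 0.885 (SD, n = 2). Without the regions at tRNA, snoRNA and snRNA genes, a setting chosen after the data had been seen, the share on X was 11.7% (exact p = 3.1e-08). With those regions kept, the share on X was near the share of bases in the conservative list (17.3% against 17.7%, exact p = 0.77). It was also near it among the regions above the median signal (17.6% against 17.7%, exact p = 1). The share without those regions was not computed in these 2 sets. The excess on IV lay in 5 of the genome's 203 windows of 500 kb, at 12000001 to 12500000, 13000001 to 14500000 and 15000001 to 15500000, with 18 to 67 regions each where 6.85 were expected. In order of position, these windows held 9, 12, 3, 4 and 2 regions of the own list of replicate 1. For replicate 2 the numbers were 14, 20, 6, 7 and 13. Outside these windows, which were chosen for their excess so that no test is given, IV held 15.3% of the regions for 15.3% of the bases. Without these windows the share on X was 18.07% against 18.12% of bases (exact p = 1), and without both the windows and the regions at tRNA, snoRNA and snRNA genes it was 13.8% against 18.12% (exact p = 0.00043). The test of all 6 chromosomes was set before the data had been seen; the attention to IV and the scan of windows were chosen after.

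**Figure D2:**
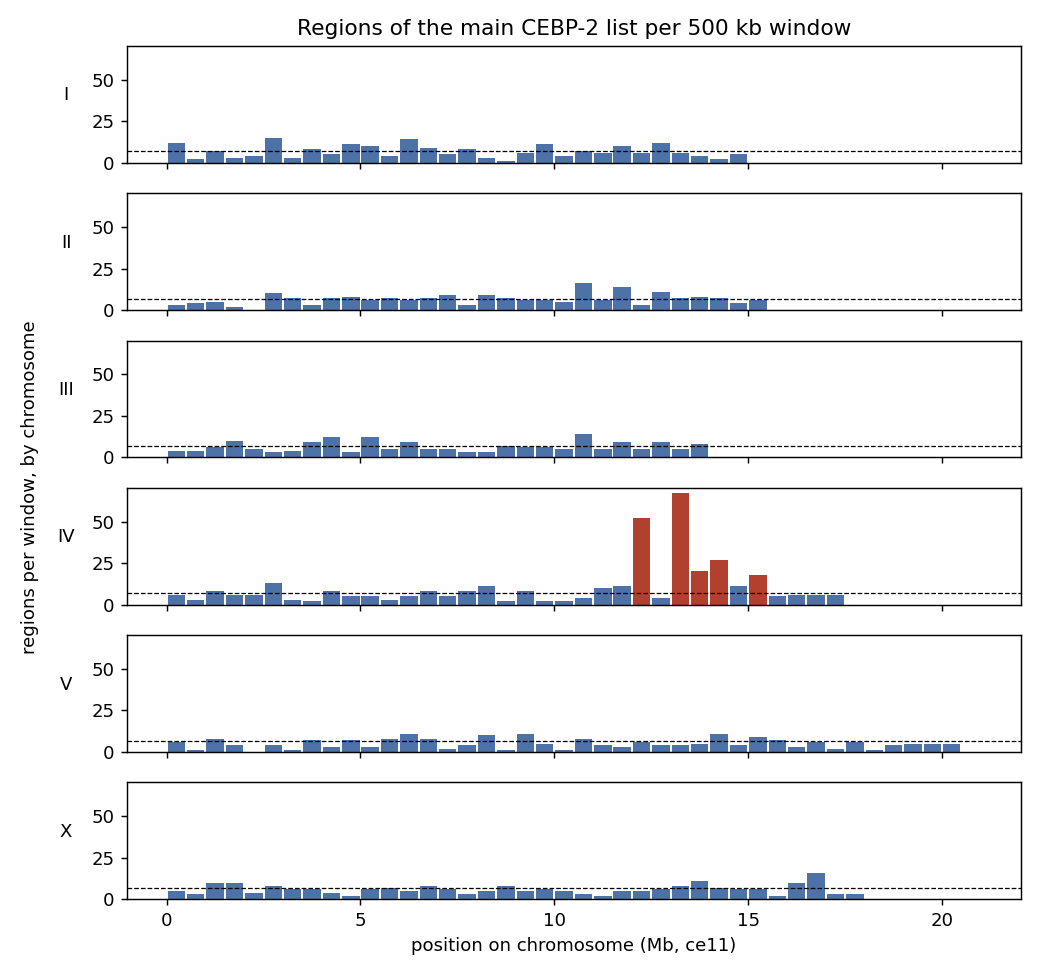
Regions of the main list per 500 kb window along the 6 chromosomes (x axis, position in Mb; y axis, number of regions). The dashed line is the number expected, 6.85, and red bars mark the 5 windows with an adjusted p under 0.05 in a Poisson test, all on IV, with up to 67 regions.

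The binding sequence of C/EBP proteins was not more frequent at summits than beside them. TTRCRYAA, in which R is a purine and Y a pyrimidine, occurred within 50 bp of 24 of 1374 summits (1.75%) and in 67 of 2748 windows centred 500 bp away (2.44%), an odds ratio of 0.711 with a 95% interval of 0.425 to 1.16 (Fisher's exact test, two-sided, p = 0.18). In the replicates' own lists the shares were 2.03% against 1.83% for replicate 1 and 2.09% against 2.09% for replicate 2. Among the 458 regions of highest signal 8 had the sequence, and among the 458 of lowest signal 10 (exact p = 0.81). The related bZIP sequences TTGCGCAA (5 summits), TGATGCAA (11 summits, 0.801% against 0.437%) and TGACGCAA (8 summits, 0.582% against 0.4003%) did not pass the exact test either, with adjusted p of 0.45, 0.30 and 0.54 over 17 motifs. The result depends on the width of the windows and on the control windows. With 100 bp to either side, a setting fixed before the data were seen, TTRCRYAA was less frequent at summits than in the flanks (3.42% against 5.13%, exact p = 0.014). Against windows at matched distance from 5' ends, a comparison fixed before the data were seen, TGACGCAA was more frequent (0.582% against 0.218%, exact adjusted p = 0.040), and TTRCRYAA was not (1.75% against 2.34%). TTGCGCAA (0.364% against 0.131%) and TGATGCAA (0.801% against 0.437%) were higher there without passing (exact adjusted p = 0.098 and 0.14). Against random windows of the same GC content, chosen after the data had been seen, TTRCRYAA was at 1.75% against 1.38%, the other direction, with an odds ratio of 1.27 and a 95% interval of 0.794 to 1.96 (exact p = 0.28). The related sequences TTGCGCAA, TGATGCAA and TGACGCAA had odds ratios of 2.64, 2.30 and 2.43 in that comparison. Their exact adjusted p were 0.21, 0.11 and 0.12, so none passed.

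Of the 17 motifs, 1 was more frequent at summits and 3 were less frequent. The E-box CACGTG, bound by basic helix-loop-helix proteins, was in 3.42% of summit windows against 1.64% of flanks (exact adjusted p = 0.0026). It did not pass in the conservative list, among the regions above the median signal or in the own lists of replicates 1 and 2 (2.44% against 2.03% and 2.88% against 2.09%). The runs of T, TTTTTTTT (3.49% against 11.6%, exact adjusted p = 7.9e-19), the GATA factor site TGATAAR (2.33% against 4.95%, adjusted p = 0.00032) and the SKN-1 site WWTRTCAT (2.77% against 4.80%, adjusted p = 0.0067) were less frequent. Summit windows held 48.0% G and C against 37.0% in the flanks. Against random windows of the same GC content, chosen as a control after the data had been seen, none of these 4 motifs differed past the threshold. In that comparison the heat shock element TTCNNGAANNTTC, the site of heat shock factor, was more frequent at 1.60% against 0.474% (exact adjusted p = 0.00012).

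**Figure D3:**
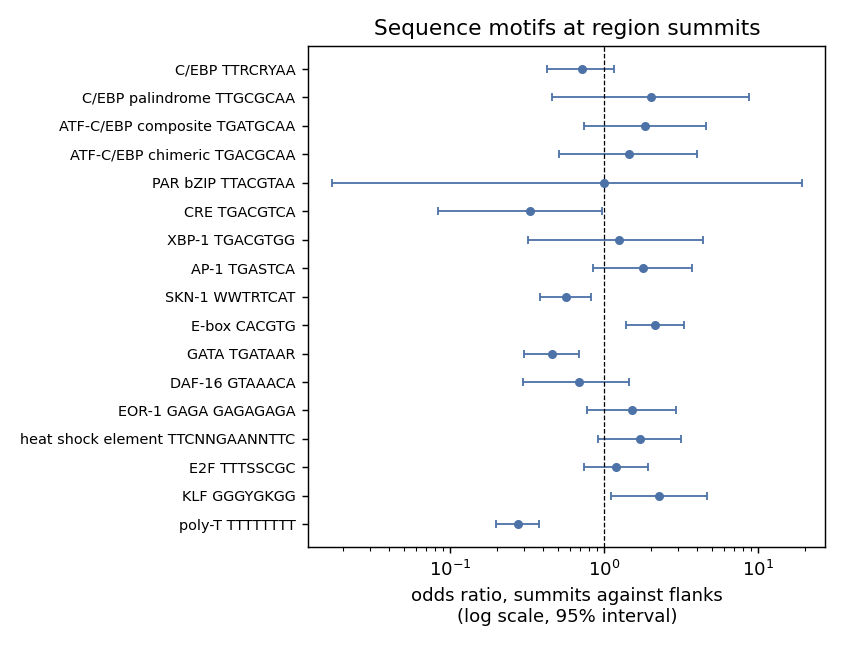
Odds ratio of each of the 17 motifs in windows within 50 bp of region summits against flanking windows (log axis, bars are 95% intervals, dashed line at 1). The interval of the C/EBP sequence, 0.425 to 1.16, spans 1, and that of the E-box, 1.38 to 3.29, lies above it.

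Part of the sequences returned by the search without a given motif lay in regions at tRNA genes. Of 13580 8-mers tested, 381 were more frequent at summits (Fisher's exact test, one-sided, adjusted p under 0.05). The 10 with the lowest p were AGTGGTTA, ACCACTCG, CTGAGCTA, AACCACTC, GGGTTCGA, CCACTCGG, ACTGAGCT, CTAACCAC, GCTCTACC and CTCGGCCA. AGTGGTTA was in 49 summit windows (3.57%) and 5 flank windows (0.182%), with an adjusted p of 1.5e-14. CTGAGCTA, which reads TAGCTCAG on the other strand as in the box A promoter element inside tRNA genes, was in 48 summit windows, of which 45 lay in regions at tRNA genes. GGGTTCGA, a sequence of the box B element, was in 50, of which 37 lay at tRNA genes. Others of the 10 lay there less often: AGTGGTTA in 25 of 49 summit windows, ACCACTCG in 14 of 40, CCACTCGG in 12 of 38, AACCACTC in 10 of 37 and CTCGGCCA in 10 of 38. Without the regions at tRNA, snoRNA and snRNA genes, 101 8-mers of 10475 passed, led by ACCACTCG and CCACTCGG with 20 summit windows and 1 flank window each.

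By the promoter window, ribosomal protein, respiratory chain and histone genes were targets more often than other genes. No control immunoprecipitation was analysed, so recovery of heavily transcribed genes whatever the tagged protein remains open for these lists. The promoter regions gave 395 target genes among 19973 protein-coding genes. Of 78 ribosomal protein genes 11 were targets (14.1% against 1.93% of other genes, Fisher's exact test, adjusted p = 9.3e-06 over 25 lists), and the replicates' own lists held 4 and 9. The strongest were rpl-3 (signal 284.1), rpl-12 (200.9; IV, 13240546 to 13240815), rpl-15 (171.6; IV, 654801 to 655070) and rpl-35 (156.5; III, 7854550 to 7854819), all encoding proteins of the large subunit. Of 34 respiratory chain genes 6 were targets (17.6% against 1.95%, exact adjusted p = 0.00061), but the own lists held 0 and 1. They were led by the cytochrome c oxidase genes cox-6A (107.3; III, 5080737 to 5081006), over the snRNA gene F54D8.7, cox-5B (89.6; I, 9788576 to 9788845), cox-11 (78.9; IV, 13243823 to 13244092, in a coding exon of JC8.4) and cox-5A (77.3; III, 12905011 to 12905280). Of 72 histone genes 8 were targets (11.1% against 1.94%, exact adjusted p = 0.00072), with 2 and 1 in the own lists. They included his-37 (112.9; V, 9546895 to 9547164), his-60 (93.4; IV, 7488363 to 7488632, in a coding exon of his-59), his-47 (91.2; IV, 11400195 to 11400464, overlapping his-58) and his-61 (82.8; IV, 7486668 to 7486937, in a coding exon of his-62). Of the 8 regions, 6 overlapped a histone gene other than the target. Their summits lay in a coding exon of that other gene or 77 to 109 bp from it. The 5' end of the target was 506 to 762 bp away, so these regions lay closer to another histone gene than to the 5' end assigned. Histone genes occur in near-identical copies, so which copy the reads came from is uncertain. The regions of his-59, his-60 and his-61 lay together at IV, 7486668 to 7488632. The test counted such neighbouring genes as independent, so the histone p-value may be too small. With a promoter window of 500 bp upstream only, ribosomal proteins were the 1 list that passed. Among the regions above the median signal ribosomal proteins and histones passed and the respiratory chain did not (exact adjusted p = 0.057).

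No list of stress or immune genes passed the test in the main list of targets. None of 8 irg genes, named for their response to infection, 7 genes of the p38 immune pathway, 32 aminoacyl-tRNA synthetase genes, 33 proteasome genes, 8 genes of the mitochondrial and 14 of the endoplasmic reticulum unfolded protein response was a target. The number expected was at most 0.653 in each of these lists, so a lower rate of binding was not detectable. None of 256 lectin and lysozyme genes was a target where 5.06 were expected (exact adjusted p = 0.069). Of 47 autophagy and lysosome genes 4 were targets, lgg-1, epg-7, atg-7 and sqst-1 (8.51% against 1.96%, exact adjusted p = 0.069), named here after their values were seen. The result of both lists depends on how targets are assigned and on the set of regions, by settings that were fixed before the data were seen. The own lists of replicates 1 and 2 held 0 and 0 of the autophagy and lysosome genes. The conservative list and the regions above the median signal held 2 each (exact adjusted p = 0.74 and 0.63). With a promoter window of 500 bp upstream only, 3 were targets (6.38% against 1.03%, exact adjusted p = 0.11). With a promoter window from 2 kb upstream to 500 bp downstream 7 autophagy and lysosome genes were targets (14.9% against 3.07%, exact adjusted p = 0.0036). With all genes whose window holds the summit as targets they were 5 (10.6% against 2.33%), and lectins and lysozymes were at 0 against 2.38%, each with an exact adjusted p of 0.026. With the 2 kb window 3 lectin and lysozyme genes were targets (1.17% against 3.12%, exact adjusted p = 0.35). In the conservative list 1 was (exact adjusted p = 0.68). Of 28 bZIP genes 1 was a target where 0.554 were expected (exact p = 0.43). It was cebp-1, the other C/EBP family gene of the lists, with a region 753 bp upstream at X, 1454486 to 1454755 (signal 76.5). That region was in neither replicate's own list.

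The region nearest to cebp-2, at I, 6253918 to 6254187, had its summit 469 bp beyond the end of the gene, in an intron of lpd-2, with a signal of 73.3. It was in the own list of replicate 1 but not in that of replicate 2. Its target by promoter window was let-611, whose 5' end lay 982 bp from the summit. In all, 5 regions lay within 50 kb of cebp-2 where 1.38 were expected (exact Poisson test, one-sided, p = 0.013), the strongest at 6264993 to 6265262 with a signal of 203.0. The labels describe an inserted transgene of cebp-2, so reads here come from the native locus and from the transgene and cannot be separated in the files.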

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

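The ranked list behind the main list held 116 peaks with a score of at least 830 that were absent from the main list, a signal in data that the comparisons do not use. Among them was the peak with the highest signal value of the series, 3485.14, at X, 15810950 to 15811197, which had values of 1238.58 and 2415.89 in the ranked lists of replicates 1 and 2. Of the 20 ranked peaks of highest signal, 14 were among the absent ones. Of the 116 peaks, 13 (11.2%) overlapped an annotated gene, against 78.3% of the main regions, and 0 overlapped a tRNA, snoRNA or snRNA gene. The file headers state that the thresholded lists also derive from a further file whose content is not named; whether that file removed these peaks was not tested.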

How the results depend on the processing

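The overlap of replicates, the promoter share and the tRNA gene share kept their direction and stayed past the threshold under all alternatives run for them. Over all results, 69 of 101 alternatives left the direction and the call, or a count within 1.5 times, and the causes of the others were not tested. A count can stay within that limit while its members change. With GC-matched windows 1 motif passed, the heat shock element and not the E-box. Motifs less frequent at summits went from 3 to 0 there. Settings that leave out small RNA gene regions or dense windows, GC-matched windows, and the overlap of replicates against random peaks of the ranked lists were chosen after the data had been seen. The X share was 15.6% with unmerged peaks, with an exact p of 0.040 before and 0.080 after adjustment over 6 chromosomes (0.052 and 0.10 in the main list), 11.7% without small RNA gene regions, 13.8% against 18.12% of bases without these and the dense windows (exact p = 0.00043, adjusted 0.0026), and 18.07% against 18.12% of bases without the dense windows alone; it was 17.3% in the conservative list and 17.6% above the median signal, both against 17.7%; in the own lists it was 17.1 to 18.3%. The share on IV was 15.3% without the dense windows and 15.8% without small RNA gene regions as well, as their removal entails. The C/EBP share was 3.42% against 5.13% with 100 bp to either side, lower at an exact p = 0.014, 1.75% against 1.38% for GC-matched windows, and 2.03 to 2.09% in the own lists, equal to or above the flanks. In the regions of highest signal it was 2.18% for the regions above the median signal, 2.36 to 2.44% in the own lists, 2.02% without dense windows, 1.85% without small RNA gene regions, 2.19% without both and 3.49% with 100 bp, each equal to or above the regions of lowest signal and none past the threshold. Enriched motifs numbered 0 in the conservative list, 0 above the median signal, 0 to 1 in the own lists (the heat shock element in replicate 1), 2 without dense windows, 3 with 100 bp and 5 against windows matched for distance to 5' ends (TGACGCAA, the E-box, the GAGA repeat of EOR-1, the heat shock element and the KLF site). Enriched k-mers numbered 232 above the median signal, 10 to 62 in the own lists, 101 without small RNA gene regions, 96 without dense windows as well, and 650 6-mers. Enriched gene lists numbered 1 in each own list and 1 with the promoter of 500 bp; the respiratory chain did not pass above the median signal, and autophagy and lysosome passed with the wider promoter and with all genes whose window holds the summit. The own lists hold fewer regions, which limits such counts. No paired analysis was possible because there is 1 group.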

Other observations

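Of the tests below, those of small RNA genes on IV, GC content and tRNA gene copies were written before their values were seen, and the others after; every pattern was noticed in the same data.

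Some regions on X held a sequence known from the sites that recruit the dosage compensation complex to this chromosome. GCGCAGGG, the core of that motif, was within 50 bp of the summit in 10 of 215 regions on X (4.65%) and 4 of 1159 on the autosomes (0.345%). Of the 7 regions on X among the 20 of highest signal, 4 held it. Outside these 20 it was in 6 of 208 regions on X (2.88%) and 4 of 1146 on the autosomes (0.349%). The sequence was chosen in the same summits, so no test of its excess is given, and 81 of its 314 sites in the genome lie on X, which holds 17.7% of bases. In the own lists 3.25% and 2.88% of summits held it, against 1.02% in the main list and 0.109% in the flanks.

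Some of the 8-mers that remained outside annotated small RNA genes belonged to a repeated sequence. GCATGGCCGAGTGGTTA, which resembles the start of a tRNA gene, occurs 51 times in the genome, and 14 of these sites (27.5%) lay in main regions, which cover 0.377% of the genome. None of the 14 regions overlapped an annotated tRNA, snoRNA or snRNA gene. The sequence was assembled from 8-mers chosen in the same windows, so no test of its excess is given. Reads of repeats can map to several copies, and mapping quality was not analysed here.

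Regions were concentrated in 5 windows of IV, with 184 of 1374 regions (13.4%) in 2.49% of the genome. Small RNA genes there did not account for it, since without regions at tRNA, snoRNA and snRNA genes IV held 28.9% of regions (exact p = 1.9e-21). Binding at piRNA genes, which lie in large numbers in the windows from 13.5 Mb, did not either: 5.43% (2.98 to 9.71%) of the regions overlapped one, against 28.3% for random placement in the same windows. The windows with the most regions, 52 and 67, held 26 and 11 piRNA genes, so the gap need not mean that regions avoid these genes. A broad rise of the signal, as extra copies of the segment in this strain would give, may contribute. Peaks under the score limit had a median signal 1.42 times higher in these windows than elsewhere, and 1.33 and 1.37 times higher in replicates 1 and 2 (permutation p = 1e-05 each, the smallest 100000 resamples can give). The window 14500001 to 15000000 was not dense, with 11 regions. Its median signal was 28.0, the highest of the other windows, and the lowest of the dense windows was 27.9. The test does not separate extra copies from binding in these windows, which were chosen for their many regions in the same lists. Copy number itself was not measured, and no biological explanation given by the design was tested.

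Regions were concentrated at tRNA, snoRNA and snRNA genes, at 17.2% of regions. GC content did not account for it, since 0.970% of GC-matched random windows lay at such genes. Reads shared between fully identical copies were unlikely to be the whole cause: of 143 tRNA genes of unique sequence 17.5% (12.1 to 24.5%) had a region, against 0.473% by chance. The share was higher, 32.4%, among the 469 genes with an identical copy (exact p = 0.00048), so shared reads may add to it. Reads shared between copies that differ at a few bases were not examined, so shared reads in that wider sense are not excluded. Recovery of heavily transcribed genes whatever the tagged protein remains open, since 14.1% of ribosomal protein genes but 0 of 6 vitellogenin genes were targets, too few to decide, and no control immunoprecipitation was analysed.

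The regions near cebp-2 may reflect copies of the transgene. Within 20 kb of the gene, 26 peaks under the score limit had a median signal 1.62 times that of 40 kb windows, at the 99.6th percentile of 2444 windows. The ratios were 1.40 and 1.42 in replicates 1 and 2, at percentiles 99.1 in both. This does not separate extra copies from binding at the locus, and the ends of the inserted fragment are not given in the sources used here.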
